A study of Mus musculus with 6 samples.

How the data were processed

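The series holds RNA sequencing of germinal vesicle oocytes from 3 Lsd1 KO and 3 Control samples of mixed C57BL/6 and 129 background. Per the labels, each sample held 100 oocytes, lysed without RNA extraction, and cDNA was amplified with the NuGEN Ovation system before fragmentation and preparation of paired-end TruSeq libraries. The deposited files give, per the labels, 1 column of raw read counts per gene for each sample, made by the authors, and the values were whole numbers in all 6. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.7, HTSeq 0.5.3p9 and the mm9 genome. Their options, the gene annotation, and whether counting used strand are not given in the sources used here. Reads were not analysed here.

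The files hold 23284 gene symbols, of which 18946 had a count in at least 1 sample. Totals ran from 10735422 to 13035045 counts, a ratio of 1.21 between the highest and lowest. Counting noise was small beside the spread between replicates: the chi-square per degree of freedom of replicate pairs was 21.2 to 47.1, and the common biological coefficient of variation was 27.2%. Positions, lengths and GC content came from GENCODE release M1 on NCBIM37, the assembly of mm9, for 21709 symbols with a unique position. The strand and overlap of neighbouring genes were read from the same annotation.

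Samples were grouped by the genotype in their labels, and the test took the 3 biological replicates per genotype of the series design as independent. Genes were kept by edgeR's filterByExpr (minimum count 10), which left 12935. Libraries were scaled by TMM, and Lsd1 KO was compared with Control by the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Every adjusted p for a gene comes from this test unless another is named. Standard errors of log2 fold changes were derived from the fitted values and the test statistic. Principal components and correlations used log2 CPM with a prior count of 2. Tables and figures used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.

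The gene lists, the comparisons, the rule for named genes and most alternatives were fixed before the data were examined. The 24 lists covered meiosis, oocyte, chromatin, germline, stress, histone, ribosomal and Zfp genes and markers of granulosa, theca and blood cells; 1127 entries matched a symbol, 8 of them by synonym, and 6 did not. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry, each adjusted over the 24 lists, and calls were also counted with p adjusted over the list alone. Named were Kdm1a and Cdc25b, and the 10 largest rises and 10 largest falls among genes past the threshold with at least 10 CPM in the higher group and no overlap between groups, leaving out bare gene models. No overlap arises by chance for 10% of genes with 3 samples against 3. In each list up to 4 passing members with the smallest adjusted p were named, and in the lists of other cells also the 2 most abundant members. Other genes are said to be named after their values were seen. The values of 1 gene that the rule names are not reported here.

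The test was tried on simulated data with 200 of 12935 genes changed, drawn only from genes above a minimum mean level. Recovery of less abundant genes was therefore not tried. Far fewer genes were changed than the 21.3% called in the data, so the recovery and the share of false calls hold for this simulated setting only. edgeR recovered 50% of genes changed by log2 1 and 95% of those changed by log2 2, with median estimates of 0.99 and 2.00 and 13 false calls (8.23% of calls). DESeq2 1.42.0 recovered 58% and 95% with 30 false calls (16.4%), and limma-voom 50% and 93% with 12 (7.74%). A length trend imposed on data without changed genes gave 2442 calls before and 0 after the length and GC correction. The imposed trend was steeper than that in the data and the same in all libraries of a genotype. The trial therefore does not show how well the correction works on these data. In a trial of camera a list raised by log2 1 had an adjusted p of 9.38e-40, and 1 other list, which was not raised, was called. The simulated genes were drawn independently of each other. The trial therefore does not show how camera behaves when the genes of a list are correlated.

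Alternatives planned beforehand were DESeq2 size factors, upper-quartile scaling, scaling to library totals, the DESeq2 Wald test, limma-voom, no filter, a filter of 10 CPM in 3 libraries, a block for replicate number, each library left out in turn, an adjusted p under 0.01 and an absolute log2 fold change of at least 1. Chosen after seeing the data were a per-library correction for transcript length and GC content (loess, span 0.5), a covariate of summed immune marker level, thinning of all libraries to the smallest total, and limma-voom with cyclic loess. These made 20 settings beside the main one. All 10 splits of the 6 samples into 3 against 3 were also fitted.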

Results

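RNA was sequenced from fully grown mouse oocytes at the germinal vesicle stage, the stage at which an oocyte is arrested in prophase of the first meiotic division before it resumes meiosis. Oocytes came from females 4 to 6 weeks old, 48 hours after 5 IU of gonadotrophin from pregnant mare serum, a hormone that stimulates follicle growth. They were either deleted for Lsd1 (the Lsd1 KO group) or had the control genotype (the Control group), with 3 biological replicates per genotype and 100 oocytes in each sample. Lsd1 is the common name of Kdm1a, a flavin-dependent histone lysine demethylase that works in the CoREST corepressor complex. The samples were compared to ask how loss of this enzyme changes the transcripts that the oocyte holds before meiosis resumes. Total counts in genes were 12334683, 11300910 and 10764095 in Lsd1 KO replicates 1 to 3, and 10735422, 13035045 and 11768098 in Control replicates 1 to 3. Between 15762 and 16815 genes had a count in each library, and the 10 most abundant genes took 6.85% to 10% of the counts. The ribosomal precursor Rn45s took 1.93%, 0.895% and 1.88% in Lsd1 KO and 1.81%, 0.630% and 1.14% in Control. On log2 values, Pearson's r across genes was 0.955 to 0.972 between libraries of one genotype and 0.900 to 0.927 between genotypes; genes are not independent replicates. The first principal component carried 53.9% of the variance and placed the 3 Lsd1 KO libraries at -55.6, -37.6 and -56.1 and the 3 Control libraries at 50, 57.7 and 41.6. The second component (15.2%) set Control replicate 3 apart, at -54.6, and the third (14.8%) set Lsd1 KO replicate 2 apart, at -53.7. Levels are CPM after TMM scaling, given as mean ± SD (n = 3 per genotype). Log2 fold changes are Lsd1 KO over Control, given ± SE, with Benjamini-Hochberg adjusted p from edgeR's quasi-likelihood test.

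The deleted gene itself, Kdm1a, was measured first. Its level was 3.27 ± 0.487 CPM in Lsd1 KO and 63.6 ± 16.6 CPM in Control, a log2 fold change of -4.28 ± 0.27 (adjusted p = 4.58e-06), which is 19.4-fold lower. The counts behind these values were 47, 31 and 36 in the 3 Lsd1 KO libraries and 799, 962 and 492 in the 3 Control libraries, so that each library carried the level its label calls for. In mm9 coordinates Kdm1a, a protein-coding gene, lies on chromosome 4 from 136106455 to 136158638. Which of its exons were deleted is not given in the sources used here, and counts cover the whole gene. Luzp1 overlaps it on the opposite strand and was at 207 ± 52.3 CPM in Lsd1 KO and 361 ± 42.5 CPM in Control.

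Cdc25b, the phosphatase that removes inhibitory phosphates from CDK1 and is needed for mouse oocytes to resume meiosis, was chosen beforehand because work on LSD1 in oocytes concerns it. It was higher in Lsd1 KO, at 139 ± 9.26 CPM against 51.4 ± 8.49 CPM in Control, a log2 fold change of 1.44 ± 0.18 (adjusted p = 3.25e-04). For Cdc25b, the Lsd1 KO libraries lay at 132 to 150 CPM and the Control libraries at 44.1 to 60.7 CPM. The gene lies on mm9 chromosome 2 from 131012685 to 131024233. Spef1 overlaps it on the opposite strand and was at 1.70 CPM in Lsd1 KO and 0.837 CPM in Control, far below the Cdc25b difference.

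**Figure D1:**
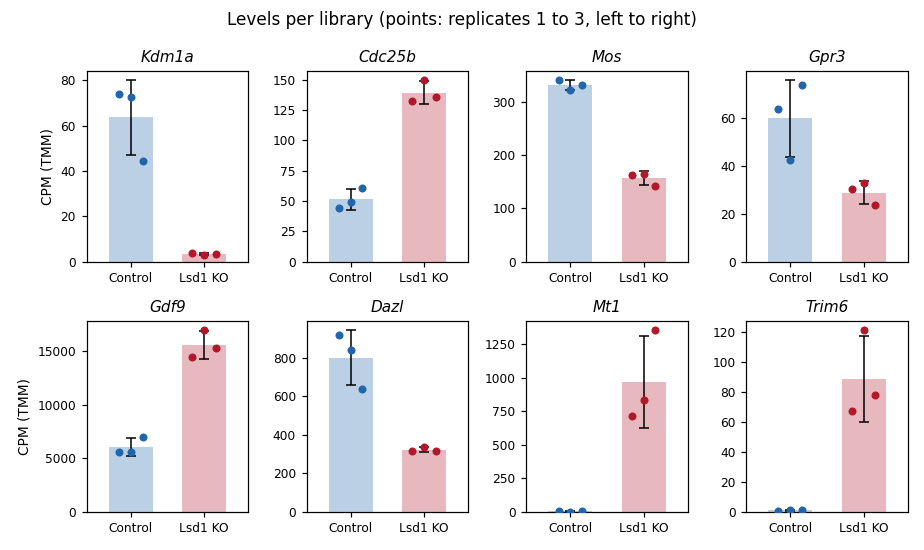
Level of 8 genes in each library, in CPM after TMM scaling on a linear axis from 0. Points are the 3 replicates of each genotype, bars are means and error bars are SD; Kdm1a, Mos, Gpr3 and Dazl were lower in each Lsd1 KO library than in any Control library, and Cdc25b, Gdf9, Mt1 and Trim6 were higher.

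Across the transcriptome, deletion of Lsd1 went with a wide change in both directions. Of 12935 genes tested, 1421 were higher and 1329 lower in Lsd1 KO, together 21.3% of the genes tested. The counts of called members in the gene lists below are to be read beside this share. Changes of at least 2-fold numbered 945 higher and 625 lower. Some of the most abundant oocyte transcripts were among the genes that rose, such as Gdf9 at 15558 ± 1264 CPM against 6057 ± 830 CPM. At an adjusted p under 0.01, 676 genes were higher and 497 lower. The number higher was 932 without Control replicate 1, and the number lower was 638, 727 and 781 without Lsd1 KO replicate 1, Lsd1 KO replicate 3 and Control replicate 2.

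**Figure D2:**
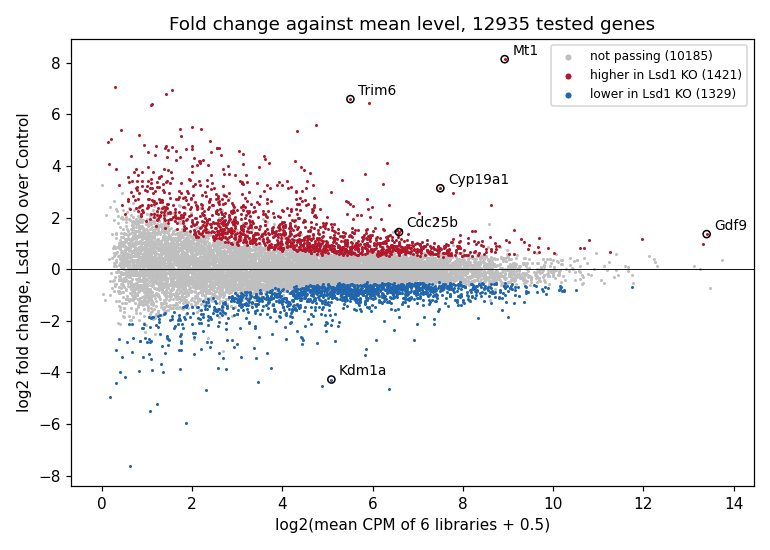
Log2 fold change, Lsd1 KO over Control, against log2 of the mean CPM of the 6 libraries plus 0.5, one point per tested gene. Red points are the 1421 genes higher and blue points the 1329 genes lower in Lsd1 KO at an adjusted p under 0.05, grey points did not pass, and 6 genes are labelled.

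The largest rise among genes past the threshold, with at least 10 CPM in the higher group and no overlap between the groups, was that of Mt1. This metallothionein, a small protein that binds zinc and other metals, went from 3.45 ± 1.38 CPM in Control to 967 ± 343 CPM in Lsd1 KO, a log2 fold change of 8.14 ± 0.38 (edgeR adjusted p = 4.00e-07). It lies on mm9 chromosome 8 from 96702989 to 96704225. Trim6, a tripartite-motif ubiquitin ligase on chromosome 7 from 111367307 to 111383666, rose from 0.906 ± 0.538 to 89.0 ± 28.7 CPM (log2 6.60 ± 0.39). Tceal8, an X-linked relative of a transcription elongation factor at 132703523 to 132706881, rose from 1.39 ± 0.751 to 118 ± 61.0 CPM (log2 6.43 ± 0.49). Cytoskeletal genes followed: the smooth muscle actin Actg2 went from 1.03 to 51.9 CPM (log2 5.60 ± 0.43) and the alpha-tubulin Tuba1a from 0.920 to 38.4 CPM (log2 5.35 ± 0.38). The other 5 genes were Ndufa4l2 (4.70 ± 0.80), the growth-factor-binding matrix protein Ltbp4 (4.69 ± 0.80), the sodium pump regulator Fxyd4 (4.68 ± 0.59), the syntaxin Stx11 (4.48 ± 0.44) and the matrix protein Smoc1 (4.44 ± 0.66), each below 1 CPM in Control and between 10.3 and 15.8 CPM in Lsd1 KO. Ltbp4 did not pass with limma-voom.

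The largest fall by the same rule was that of Cttnbp2, a cortactin-binding protein, from 55.5 ± 10.8 CPM in Control to 2.44 ± 2.1 CPM in Lsd1 KO (log2 -4.52 ± 0.51, edgeR adjusted p = 1.52e-04), followed by that of Kdm1a. It lies on mm9 chromosome 6 from 18316478 to 18465338. Several transcription regulators were in this set: Ebf3 (-3.82 ± 0.64), the zinc-finger protein Zfp423 (-3.06 ± 0.31) and the LIM-domain protein Lmo4 (-3.25 ± 0.56), which went from 10.1, 17.6 and 21.8 CPM to 0.716, 2.1 and 2.30 CPM. The others were the uronyl sulfotransferase Ust (-3.44 ± 0.44), the Toll-like receptor partner Tril (-3.44 ± 0.49), Ttc34 (-3.41 ± 0.66), the pregnancy-specific glycoprotein Psg16 (-3.26 ± 0.42) and the coronin Coro2b (-3.08 ± 0.67), the last from 102 ± 13.3 to 12.1 ± 12.1 CPM. These 10 falls and the 10 rises held their side of the threshold with each single library left out.

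Genes of meiotic resumption and the M-phase kinases changed in part, where 21.3% of all genes tested were called. Neither this list nor the cAMP and cGMP, anaphase-promoting complex and spindle lists passed as a set (camera adjusted p = 0.886, 0.513, 0.559 and 0.920). Of 28 measured members, 4 were higher, 1 was lower and 23 did not pass, the same counts when adjusted over the list alone. Beside Cdc25b, the phosphatase Cdc14b rose by log2 1.07 ± 0.18 (327 against 156 CPM), Aurora kinase A (Aurka) by 0.74 ± 0.18 and Ensa, an inhibitor of the phosphatase PP2A named here after its values were seen, by 0.90 ± 0.23. Mos, the kinase that starts the MAP kinase cascade in meiosis, fell from 333 ± 9.65 to 157 ± 13 CPM (log2 -1.08 ± 0.16, edgeR adjusted p = 0.00102). Among 18 genes of oocyte cAMP and cGMP signalling, which holds prophase arrest, 1 was lower and none higher, the same when adjusted over the list alone: Gpr3, the receptor that keeps oocyte cAMP high, went from 60.0 ± 16.1 to 28.9 ± 4.79 CPM (log2 -1.05 ± 0.23, edgeR adjusted p = 0.00784). In 26 genes of the anaphase-promoting complex and spindle checkpoint, 3 were higher and 3 lower, also when adjusted over the list alone. The complex subunits Anapc11 (1.30 ± 0.20) and Anapc4 (0.82 ± 0.18) and the separase Espl1 (0.76 ± 0.19) rose, and the checkpoint kinase Bub1b (-0.74 ± 0.19) fell. The other falls, named after their values were seen, were in the subunit Cdc27 (-0.65) and the kinase Ttk (-0.53). Of 28 spindle and centromere genes, 4 rose and none fell, with the same counts when adjusted over the list alone: the alpha-tubulin Tuba1b (1.35 ± 0.18, 348 against 137 CPM), Cdca8 (0.99 ± 0.19) and Birc5 (0.68 ± 0.17) of the chromosomal passenger complex, and the nucleotide exchange factor Rcc1 (1.22 ± 0.30). When 1 library was left out, some of these calls were lost. Aurka and Rcc1 did not pass without Control replicate 1 or 2 (adjusted p up to 0.0648 and 0.0659), nor Ensa and Espl1 without Lsd1 KO replicate 1 or Control replicate 1 (up to 0.0976 and 0.0668). Birc5 did not pass without Lsd1 KO replicate 2 or Control replicate 2 (up to 0.0556), nor Bub1b without Lsd1 KO replicate 1, Lsd1 KO replicate 3 or Control replicate 2 (up to 0.0917). Cdc27 and Ttk kept the call in 2 and 1 of the 6 such fits (adjusted p up to 0.141 and 0.177). Aurka and Cdc27 also lost the call with a correction for transcript length and GC content, and Bub1b, Ensa, Cdc27 and Ttk with an immune marker covariate.

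Of 38 measured oocyte-specific and maternal-effect genes, 7 were higher, 1 was lower and 30 did not pass, with the same counts when adjusted over the list alone. As a set they did not pass (camera adjusted p = 0.559, and 0.928 with an estimated correlation). The number lower was 2 without Lsd1 KO replicate 2 and 3 without Control replicate 3. The growth factor Gdf9, secreted by the oocyte to act on its follicle, rose by log2 1.36 ± 0.18 (edgeR adjusted p = 5.01e-04) and was at 14482 to 16950 CPM in the Lsd1 KO libraries and at 5569 to 7015 CPM in the Control libraries. Zbed3, a component of the subcortical maternal complex, went from 6866 ± 1411 to 13502 ± 2096 CPM (log2 0.98 ± 0.20), and Omt2b from 425 ± 52.5 to 878 ± 130 CPM (log2 1.05 ± 0.18). Nlrp2, a maternal-effect gene, fell from 535 ± 19.4 to 284 ± 41.1 CPM (log2 -0.91 ± 0.17). In 28 genes of maternal mRNA storage and decay, 1 was higher and 3 were lower, also when adjusted over the list alone. The deadenylase Parn rose (1.36 ± 0.20, 157 against 61.2 CPM), whereas the translational regulator Dazl fell from 801 ± 144 to 323 ± 13.5 CPM (log2 -1.31 ± 0.18, edgeR adjusted p = 6.81e-04), with the deadenylase subunit Pan3 (-0.90 ± 0.19) and the RNA-binding protein Pum2 (-0.65 ± 0.19). Pum2 lost the call without Lsd1 KO replicate 1, Lsd1 KO replicate 3 or Control replicate 2 (adjusted p up to 0.142), after the length and GC correction and with the immune covariate. Of 12 measured genes typical of the 2-cell embryo, 1 was higher and 3 were lower (1 and 4 when adjusted over the list alone). D5Ertd577e fell from 35.6 ± 8.11 to 5.74 ± 2.76 CPM (log2 -2.63 ± 0.35), the arginase Arg2 fell (-0.82 ± 0.19) and Zscan4c fell from 4.38 to 1.18 CPM (-1.89 ± 0.59). Sp110 rose (0.81 ± 0.21). Zscan4c kept its call only without Lsd1 KO replicate 3 among the 6 leave-one-out fits (adjusted p up to 0.126) and lost it with the immune covariate. Sp110 lost it without Lsd1 KO replicate 2 or Control replicate 1 (up to 0.0756) and after the length and GC correction.

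Among chromatin genes, 21 members of the LSD1 family and its corepressor complexes were measured, of which 3 were higher and 4 lower (4 and 4 when adjusted over the list alone). Apart from Kdm1a itself, the CoREST subunit Phf21a, which binds unmethylated histone tails, rose from 25 ± 2.37 to 71.3 ± 7.83 CPM (log2 1.51 ± 0.19, edgeR adjusted p = 2.84e-04). The zinc-finger subunit Zmym2 (-0.94 ± 0.19) and the repressor Rest (-0.88 ± 0.16), which recruits CoREST to neuronal genes, fell. Named after their values were seen, Chd4 (0.75) and Mta1 (0.61) of the NuRD complex were higher and Rreb1 (-0.64) lower, and these kept the call in 1, 1 and 3 of the 6 leave-one-out fits (adjusted p up to 0.107, 0.180 and 0.133). Histone methyltransferases and demethylases gave 4 higher and 7 lower of 36 (4 and 8 when adjusted over the list alone). The number lower was 2, 3 and 3 without Lsd1 KO replicates 1, 2 and 3 and 4 without Control replicate 2 or 3, and the number higher was 1 without Lsd1 KO replicate 1 or 3 and 2 without Control replicate 1. The demethylase Kdm3b fell from 43.2 ± 2.51 to 15.5 ± 3.27 CPM (log2 -1.48 ± 0.21) and the methyltransferase Setd2 from 396 ± 63.3 to 220 ± 16.8 CPM (-0.84 ± 0.18), whereas the methyltransferase complex subunit Ash2l (1.02 ± 0.19) and the demethylase Kdm5b (1.29 ± 0.33) rose. Kdm5b lost the call without Lsd1 KO replicate 1 or 3 (adjusted p up to 0.0592). The other rises, named after their values were seen, were Prdm9 (1.94) and Kdm4a (0.68), kept in 3 and 2 of the 6 leave-one-out fits (adjusted p up to 0.0722 and 0.166). The other falls, also named after their values were seen, were Kdm3a, Kdm5c, Mll2, Cxxc1 and Setd1a. They were kept in 3, 2, 2, 1 and 1 of the 6 such fits (adjusted p up to 0.0751, 0.122, 0.135, 0.0853 and 0.168).

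In the DNA methylation machinery, 2 of 20 measured genes were higher and none lower (1 and none when adjusted over the list alone). The dioxygenase Tet1, which oxidises methylcytosine, went from 9.09 ± 3.54 to 23.2 ± 7.20 CPM (log2 1.35 ± 0.33), and Dppa3, a maternal protector of DNA methylation, from 1892 ± 290 to 2973 ± 645 CPM (0.65 ± 0.20). By edgeR, Tet1 did not pass without Lsd1 KO replicate 1 or Control replicate 1 (adjusted p up to 0.0590), and Dppa3 kept the call in 2 of the 6 leave-one-out fits (up to 0.170) and lost it with the length and GC correction and with the immune covariate. Imprinted genes gave 1 higher and 4 lower of 21 (2 and 4 when adjusted over the list alone). Peg10 fell from 28.1 ± 3.65 to 7.81 ± 2.06 CPM (log2 -1.84 ± 0.27, edgeR adjusted p = 8.06e-04) and Inpp5f from 57.6 ± 9.72 to 24.6 ± 3.30 CPM (-1.23 ± 0.20). The cell-cycle inhibitor Cdkn1c (-1.30 ± 0.41) and, named after its values were seen, Mest (-0.55) were also lower, and each kept the call in 1 of the 6 leave-one-out fits (adjusted p up to 0.167 and 0.202) and lost it with the immune covariate, and Cdkn1c also with limma-voom. Zrsr1, which lies within Commd1 on the opposite strand, rose from 0.316 to 2.97 CPM (3.13 ± 0.81) and did not pass without Lsd1 KO replicate 1 (adjusted p = 0.0636).

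Germline and genome-integrity genes moved in both directions, where 21.3% of all genes tested were called. The recombination, small RNA and DNA damage lists did not pass as sets (camera adjusted p = 0.920, 0.769 and 0.886). Of 23 genes of meiotic recombination and cohesion, 2 were higher and 2 lower, also when adjusted over the list alone. Gm1564, the symbol in the files for the meiotic regulator Meioc, rose from 7.96 ± 1.01 to 104 ± 31.9 CPM (log2 3.71 ± 0.27, edgeR adjusted p = 9.18e-06), and the helicase Hfm1 rose (1.28 ± 0.29). The synaptonemal complex genes Sycp2 and Tex12 fell, from 134 ± 18.7 to 44.5 ± 1.14 CPM (-1.59 ± 0.18) and from 51.1 ± 10.7 to 14.8 ± 1.6 CPM (-1.79 ± 0.22). Transposon and small RNA pathway genes gave 4 higher and 3 lower of 24 (4 and 4 when adjusted over the list alone). Eif2c1, the older symbol of Argonaute Ago1, rose from 3.55 ± 2.02 to 14.9 ± 4.97 CPM (2.08 ± 0.42) and the helicase Mov10 from 3.25 to 9.70 CPM (1.57 ± 0.36). The piRNA methyltransferase 4921515J06Rik (Henmt1) fell from 79.8 ± 9.80 to 32.5 ± 7.94 CPM (-1.30 ± 0.22) and Mael, needed for transposon silencing, from 154 ± 26.0 to 67.5 ± 28.6 CPM (-1.19 ± 0.26). Named after their values were seen, Eif2c4 (1.69) and Drosha (0.66) were higher and Pld6 (-1.13) lower, and they kept the call in 1, 4 and 0 of the 6 leave-one-out fits (adjusted p up to 0.104, 0.0656 and 0.113). Among 29 DNA damage response and repair genes, 2 were higher and 1 lower, also when adjusted over the list alone. The end-joining ligase Lig4 fell from 150 ± 9.92 to 41.6 ± 10.7 CPM (-1.85 ± 0.20, edgeR adjusted p = 1.38e-04), and Fancd2 (1.08 ± 0.20) and the checkpoint kinase Atr (0.70 ± 0.18) rose. Atr did not pass without Lsd1 KO replicate 1, Lsd1 KO replicate 2 or Control replicate 1 (adjusted p up to 0.0752).

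Of 26 measured p53 targets and apoptosis genes, 3 were higher and 2 lower (4 and 2 when adjusted over the list alone). Cyclin G1 (Ccng1), a p53 target, rose from 20.2 ± 1.75 to 54.1 ± 11.1 CPM (log2 1.42 ± 0.21, edgeR adjusted p = 8.06e-04), the cell-cycle inhibitor Cdkn1a from 2.58 to 8.31 CPM (1.70 ± 0.43) and the survival factor Bcl2l1 from 53.9 to 89.8 CPM (0.74 ± 0.19). The related survival factor Bcl2 was rare and fell from 2.47 to 0.377 CPM (-2.68 ± 0.66), and Trp73, named after its values were seen, was also lower (-1.22). Cdkn1a lost the call without Lsd1 KO replicate 1 or Control replicate 2, Bcl2 without Lsd1 KO replicate 1 or Control replicate 1, Bcl2l1 without any of these 3 libraries, and Trp73 in 4 of the 6 leave-one-out fits (edgeR adjusted p up to 0.0746, 0.0732, 0.0774 and 0.106). Bcl2l1 also lost the call with the length and GC correction. Immediate-early and stress genes gave 3 higher and 4 lower of 22, also when adjusted over the list alone. The chaperones Hspa8 (-0.71 ± 0.17) and Hsp90aa1 (-0.69 ± 0.18) fell, at 878 against 1433 CPM and 2633 against 4238 CPM, with the phosphatase Dusp1 (-0.96 ± 0.27), while the stress transcription factor Atf4 rose (0.70 ± 0.18). The remaining members, named after their values were seen, were Hmox1 (1.68), Jund (1.34) and Hspa1b (-1.34). Each of these 7 calls was lost in at least 1 leave-one-out fit: Hspa8 without Lsd1 KO replicate 1, Hsp90aa1 without Lsd1 KO replicate 1 or Control replicate 1, Atf4 without Lsd1 KO replicate 2 or Control replicate 1 (adjusted p up to 0.0631, 0.108 and 0.0700), and the others in 4 or 5 of the 6 fits (adjusted p up to 0.194, for Jund). Atf4 also lost the call with the length and GC correction, and Hmox1 and Jund with the immune covariate.

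Genes kept silent by REST outside neurons were mostly too low to test, with 13 of 34 list members measured. Of these, 4 were higher and 1 lower (5 and 2 when adjusted over the list alone). The synaptotagmin Syt11 rose from 16.4 to 31.0 CPM (log2 0.92 ± 0.23, edgeR adjusted p = 0.0130) and the complexin Cplx1 from 2.26 to 6.64 CPM (1.55 ± 0.42). The sodium channel Scn3a rose from 0.971 to 3.76 CPM (1.95 ± 0.55). The sodium channel Scn8a, named after its values were seen, was lower (-0.77). Syt11 did not pass without Control replicate 1, Cplx1 and Scn3a passed in 2 of the 6 leave-one-out fits each, and Scn8a in 1 (adjusted p up to 0.0601, 0.0799, 0.0915 and 0.140). Developmental transcription factors, of which 15 of 61 were measured, gave 4 higher and 4 lower (5 and 5 when adjusted over the list alone). Pax3 rose from 0.166 ± 0.145 to 4.39 ± 2.56 CPM (4.62 ± 0.83) and Tbx5 from 1.52 ± 0.637 to 10.9 ± 5.85 CPM (2.83 ± 0.52). Gata4 fell from 22.4 ± 11.1 to 5.52 ± 2.39 CPM (-2.02 ± 0.41) and Hoxd13 from 5.18 ± 2.79 to 0.586 ± 0.585 CPM (-3.13 ± 0.70). Named after their values were seen, Hoxa5 (2.14) and Gata3 (0.84) were higher and Hoxd8 (-3.98) and Lhx2 (-1.14) lower. Hoxd8 held with each library left out, and Hoxa5, Gata3 and Lhx2 passed in 0, 2 and 2 of the 6 such fits (adjusted p up to 0.137, 0.0932 and 0.0938).

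Zinc-finger genes with Zfp symbols, many of which encode KRAB-domain repressors, formed the largest list, with 309 measured. Of these, 61 were lower, 30 higher and 218 did not pass (67 lower and 31 higher when adjusted over the list alone), and their median log2 fold change was -0.26. Zfp616 fell from 258 ± 35.5 to 68.2 ± 16.7 CPM (log2 -1.92 ± 0.21) and Zfp423 from 17.6 to 2.1 CPM (-3.06 ± 0.31), whereas Zfp458 rose from 4.33 ± 2.17 to 34.3 ± 3.27 CPM (2.99 ± 0.33) and Zfp940 from 6.56 ± 2.41 to 44.0 ± 1.21 CPM (2.75 ± 0.27, edgeR adjusted p = 5.92e-05). The list was lower than the other genes by camera (adjusted p = 0.0235, with the preset correlation of 0.01), but not with an estimated correlation (adjusted p = 0.155). Without Lsd1 KO replicate 3 or Control replicate 2 the camera call was lost (adjusted p = 0.0642 and 0.0906), and the members lower numbered 33 and 39, against 40 without Lsd1 KO replicate 1. Across all genes, the median transcript length was 3863 nt for genes called lower and 2641.5 nt for genes called higher. Between libraries, an exact permutation test of the slopes of level on length gave p = 0.3, where the smallest possible is 0.1. After a correction for length and GC content 57 Zfp genes were lower and 30 higher. Over all genes that correction raised the number lower from 1329 to 1609 and cut the number higher from 1421 to 1227. Camera was not run with this correction.

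Of 32 measured replication-dependent histone genes, which had median levels of 3.08 CPM in Lsd1 KO and 2.95 CPM in Control, 1 was higher and 1 lower, also when adjusted over the list alone: Hist1h4d (log2 1.54 ± 0.42, 47.1 against 16.2 CPM) and Hist1h2bc (-1.23 ± 0.28, 26.7 against 62.6 CPM). Hist1h4d did not pass without Lsd1 KO replicate 1 or Control replicate 1 (edgeR adjusted p up to 0.0870), with DESeq2 or after the length and GC correction. Of 76 ribosomal protein genes, 4 were higher and 1 lower (4 and none when adjusted over the list alone), namely Rps4y2 (1.63 ± 0.24), Rps2 (0.68 ± 0.16), Rpl23 (0.75 ± 0.20), Rpl36a (0.84 ± 0.22) and, named after its values were seen, Rpl31 (-0.70). Rpl23 and Rpl36a did not pass without Lsd1 KO replicate 1, Lsd1 KO replicate 3 or Control replicate 2 (adjusted p up to 0.0733 and 0.0715), and Rpl31 passed in 2 of the 6 leave-one-out fits (up to 0.141). Rps2, Rpl23 and Rpl36a did not pass after the length and GC correction, nor Rpl23 with the immune covariate.

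**Figure D3:**
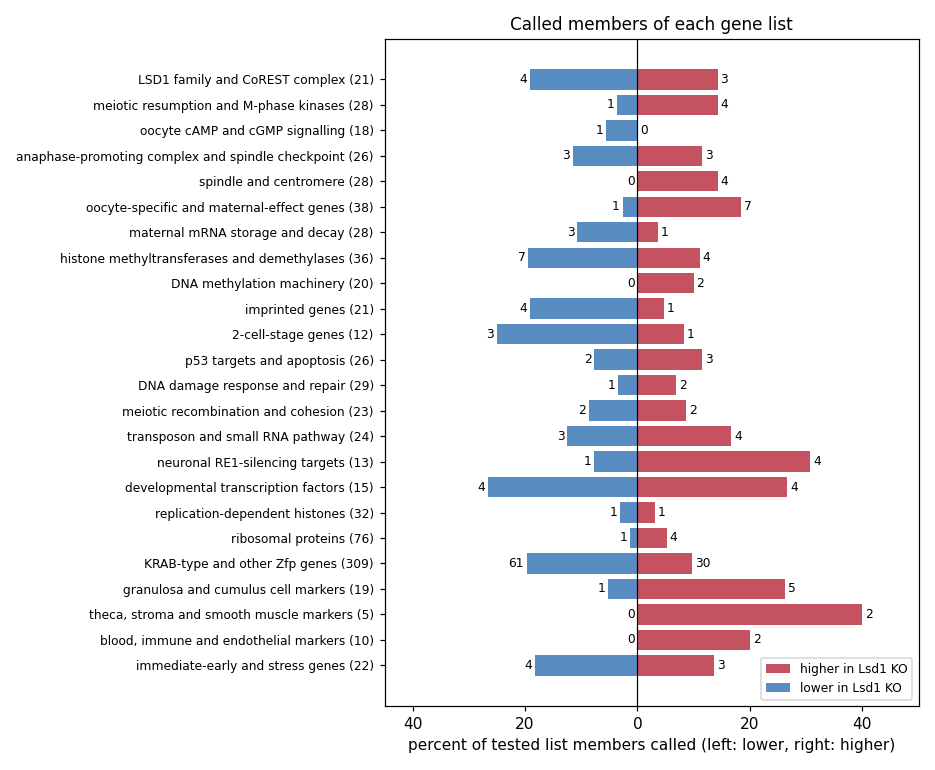
Percent of the measured members of each gene list that were lower (blue, to the left) or higher (red, to the right) in Lsd1 KO at an adjusted p under 0.05. Tested members stand in brackets and the number called beside each bar; the Zfp list had 61 lower and 30 higher of 309, and the granulosa list 5 higher and 1 lower of 19.

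Markers of other ovarian cells were examined because oocytes were released by puncturing follicles. Of 19 measured granulosa and cumulus cell markers, 5 were higher, 1 was lower and 13 did not pass (6 and 1 when adjusted over the list alone), with a median log2 fold change of 1.31. Aromatase (Cyp19a1), which makes oestrogen in granulosa cells, rose from 36.8 ± 11 to 324 ± 82.8 CPM (log2 3.14 ± 0.26, edgeR adjusted p = 1.78e-05) and lies on mm9 chromosome 9 from 54013744 to 54115917. The prostaglandin synthase Ptgs2 rose from 1.83 ± 0.352 to 18.7 ± 3.73 CPM (3.35 ± 0.33) and Hsd17b7 from 110 ± 16.3 to 185 ± 25.3 CPM (0.75 ± 0.18). The nuclear receptor Nr5a2 fell from 69.4 ± 3.10 to 28.7 ± 3.99 CPM (-1.28 ± 0.18). Inha (1.36) and Gja1 (1.90), named after their values were seen, were higher, with overlap between the libraries of both genotypes. Hsd17b7 did not pass without Control replicate 2 (adjusted p = 0.0560), and Inha and Gja1 passed in 2 and 3 of the 6 leave-one-out fits (up to 0.255 and 0.104). The list was higher than other genes by camera (adjusted p = 0.0124), but not with an estimated correlation (adjusted p = 0.818), nor without Lsd1 KO replicate 3 or Control replicate 2 (adjusted p = 0.0642 and 0.0693). In Control, 4 of its 19 members were at 10 CPM or more.

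Among 5 measured markers of theca, stroma and smooth muscle, 2 were higher and none lower (4 and none when adjusted over the list alone). The proteoglycan Dcn rose from 0.414 ± 0.169 to 7.57 ± 0.386 CPM (log2 4.14 ± 0.48, edgeR adjusted p = 1.92e-04) and the matrix protein Postn from 2.25 ± 0.0640 to 6.39 ± 3.02 CPM (adjusted p = 0.0329). Postn kept the call in 1 of the 6 leave-one-out fits (adjusted p up to 0.139) and lost it with limma-voom and with the immune covariate. The most abundant members, Myh11 at 268 ± 21.3 against 205 ± 10 CPM (log2 0.38 ± 0.16, adjusted p = 0.114) and Fn1 at 16.9 ± 2.75 against 12 ± 1.6 CPM (0.50 ± 0.25, adjusted p = 0.184), did not pass. By camera the list was higher (adjusted p = 0.0235), but not with an estimated correlation (adjusted p = 0.463) or on ranks (adjusted p = 0.0503). Of the 6 fits with 1 library left out, the list passed only without Control replicate 3, and its adjusted p reached 0.320 without Lsd1 KO replicate 3. Of 10 blood, immune and endothelial markers, 2 were higher and none lower, also when adjusted over the list alone: the macrophage marker Cd68 (1.86 ± 0.54, 18.3 ± 10.8 against 5.05 ± 3.39 CPM, with overlap between the genotypes) and the endothelial receptor Tek (0.73 ± 0.22, 47.5 against 28.6 CPM). Each kept the call in 2 of the 6 leave-one-out fits (adjusted p up to 0.113 and 0.120) and lost it with the immune covariate. Cd68 is itself 1 of the markers summed in that covariate, so its loss there carries no weight. Cd68 also lost the call with limma-voom and the length and GC correction. The most abundant member, Pecam1, was at 60.0 ± 16.3 against 48.9 ± 6.06 CPM and did not pass (adjusted p = 0.355). The levels of 6 immune markers (Ptprc, Lyz2, Cd52, Tyrobp, Fcer1g and Cd68) were summed, in CPM of library totals without TMM scaling. Their sum was 125, 5.84 and 93.3 CPM in Lsd1 KO replicates 1 to 3 and 28.2, 4.14 and 30.9 CPM in Control replicates 1 to 3. With this sum as a covariate, an alternative chosen after seeing the data, 1093 genes were higher and 947 lower.

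**Figure D4:**
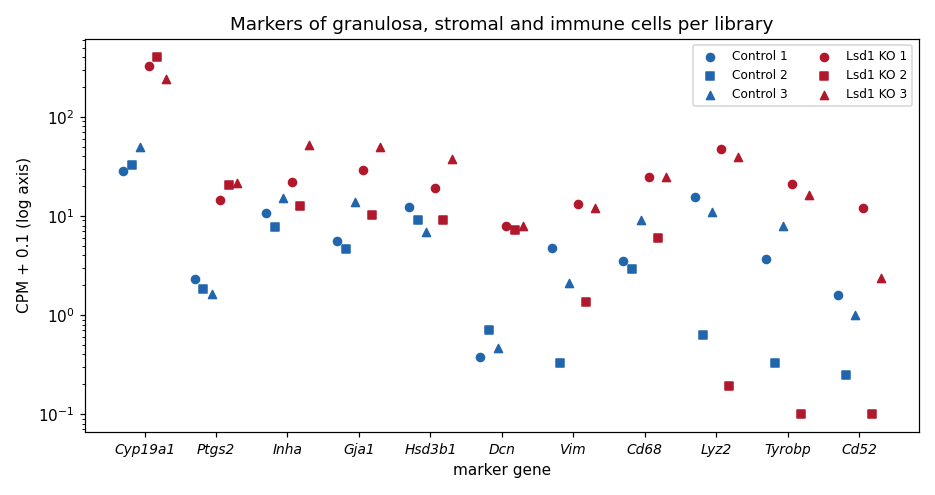
Level of 11 marker genes of granulosa, stromal and immune cells in each of the 6 libraries, as CPM plus 0.1 on a log axis. Each point is 1 library, with colour for genotype and shape for replicate; Cyp19a1, Ptgs2 and Dcn separated the genotypes, while Lyz2, Tyrobp and Cd52 lay lowest in replicate 2 of both genotypes.

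Tested as sets by camera against all other genes, 3 of the 24 lists passed: the granulosa and the theca, stroma and smooth muscle markers were higher and the Zfp genes lower. With an estimated correlation between genes none of the 24 passed (2 at an unadjusted p under 0.05, the Zfp and theca lists). Next by the preset correlation came the histone methyltransferases and demethylases, lower with an adjusted p of 0.151. That list passed without Lsd1 KO replicate 1 (adjusted p = 0.0418) or Control replicate 1 (0.0482), and the blood, immune and endothelial markers, which had an adjusted p of 0.448, were higher without Lsd1 KO replicate 2 (0.0189). By fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, the Zfp and theca lists passed (adjusted p = 0.00739 for both) and the granulosa list did not (adjusted p = 0.0689). In 6 lists the median, the mean and the direction of the camera test differed in sign: the LSD1 and CoREST, spindle, DNA methylation, meiotic recombination, ribosomal protein and stress lists, whose medians were 0.02, -0.04, -0.04, -0.18, -0.07 and 0.16.

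Some values cannot be assigned to a single gene. Whether counting used strand is not given in the sources used here, so reads cannot be told apart from those of an overlapping gene on the opposite strand for Ndufa4l2 (Shmt2), Gpr3 (Cd164l2), Arg2 (Vti1b), Zrsr1 (Commd1), Rps4y2 (Tmtc1), Fn1 (Apol7d), Rpl31 (Tbc1d8) and Mest (Copg2), and for Cttnbp2, Tril, Ttc34, Coro2b, Phf21a, Cdc14b, Cdca8, Rcc1, Nlrp2, Kdm3b, Bcl2, Fancd2, Atr, Hfm1, 4921515J06Rik, Syt11, Scn3a, Rps2, Zfp940, Zfp616, Pecam1, Kdm4a, Eif2c4, Trp73, Jund, Hoxa5, Gata3, Hoxd8 and Lhx2, whose antisense neighbours are gene models, pseudogenes or small RNAs. How reads that match near-identical copies were treated is not given either, and this leaves the values of Actg2, the tubulins, the histones, the ribosomal proteins, Omt2b, Zscan4c and the clustered Zfp genes uncertain.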

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

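The length and GC correction, the immune covariate, thinning and cyclic loess were chosen after seeing the data. Kdm1a (log2 -4.49 to -4.16) and Cdc25b (1.30 to 1.56) kept direction and call in all 20 settings. Of 102 named genes that passed, 60 were the same in every setting that tested them and 0 reversed. These settings include the stricter thresholds, which can only end calls. An adjusted p under 0.01 ended 32 and an absolute log2 fold change of at least 1 ended 28. The filter of 10 CPM in 3 libraries left some named genes untested, such as Dcn and Pax3. With each single library left out 71 were kept. The length and GC correction ended 11 and the immune covariate 9, among them Cd68, which is part of that covariate. Among genes named after their values were seen, the first also ended the calls of Cdc27, Hoxa5, Inha, Mll2, Mta1, Scn8a and Setd1a. It further ended those of Cbr1, Ftl1, Gclm, Gsto2, Nqo1 and Sirt5. The covariate ended those of Cdc27, Chd4, Eif2c4, Ensa, Gja1, Hmox1, Hoxa5, Inha, Jund, Kdm4a, Kdm5c and Mest. It also ended those of Mta1, Pld6, Rreb1, Setd1a, Ttk, Cbr1, Ftl1, Kat2a and Nqo1. Scaling by upper quartile or library totals ended those of Hspa1b, Jund, Pld6 and Rpl31, and DESeq2 size factors those of Mest and Mta1. The DESeq2 Wald test ended those of Hist1h4d, Gja1, Hoxa5, Gsto2 and Slc30a3, and limma-voom those of Ltbp4, Cdkn1c, Postn, Cd68, Hoxa5, Inha, Mta1, Cbr1, Ftl1, Gsto2 and Nqo1. With cyclic loess Postn, Cd68, Hoxa5, Inha, Mest, Rpl31, Setd1a, Ftl1, Gsto2 and Mtf1 were lost. With thinning Hoxa5, Kdm4a, Mta1, Pld6 and Cbr1 were lost, and with no filter Hoxa5, Pld6 and Ttk. Among the genes that the filter of 10 CPM still tested, Rpl31 was lost.

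With 1 library left out, genes higher numbered 932 (without Control replicate 1) to 1466 (without Control replicate 3), and genes lower 638 (without Lsd1 KO replicate 1) to 1346 (without Control replicate 3). They were 727 without Lsd1 KO replicate 3 and 781 without Control replicate 2. The cause was not tested. With all libraries, the other settings apart from stricter thresholds gave 1093 (immune covariate) to 1682 (no filter) higher and 947 (immune covariate) to 1609 (length and GC correction) lower, and the DESeq2 Wald test 1624 and 1586. Stricter thresholds gave by construction fewer: 676 and 497 at an adjusted p under 0.01, 945 and 625 at an absolute log2 fold change of at least 1. Leaving out 1 library kept 55.8% to 81.9% of the calls, DESeq2 98.9% and limma-voom 93.6%. The length and GC correction turned the balance, with 1227 higher and 1609 lower, and leaving out Control replicate 1 gave 48.4% higher, against 51.7% with all libraries. No setting moved the median log2 fold change of all genes by over 0.1.

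Of the 3 lists that passed camera, 0 passed with an estimated correlation, 2 on ranks, and 0 to 3 lists with 1 library left out (0 without Lsd1 KO replicate 3 or Control replicate 2). The cause was not tested.

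Between samples with the same replicate number the deviations from the genotype means correlated at -0.03, 0.11 and -0.02 for numbers 1 to 3, so the numbers were not taken as pairs. Replicate 2 had the lowest share of Rn45s (0.895% and 0.630%) and the lowest immune marker sum (5.84 and 4.14 CPM of library totals) in both genotypes. With a replicate block 1270 genes were higher and 1098 lower, 82.4% of the calls were kept, and 3 lists passed. Named genes not called with the block were Pum2, Dppa3, Cdkn1c and Postn. Among those named after their values were seen, Hoxa5, Jund, Kdm4a, Kdm5c, Mest, Mll2, Mta1 and Pld6 were not called with it. Nor were Scn8a, Setd1a, Ttk, Cbr1, Gsto2, Mtf1 and Sirt5. With a filter of 10 CPM in 3 libraries, which tests fewer genes, 1175 were higher and 1016 lower. With all libraries thinned to the smallest total, 1398 were higher and 1322 lower.

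As to other splits of the 6 samples into 3 against 3, 10 splits cannot give a share under 0.05; the real split gave 1421 genes higher and 1329 lower, and the highest of the others 0 for both, so that 1 of the 10 gave as many.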

Other observations

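The gene groups described first were chosen after their values were seen, and so were the tests of the length slopes, of the Cyp19a1 and Ptgs2 ratio and of the correlation of other granulosa markers; no enrichment test was run on the chosen groups. Of 37 measured antioxidant and detoxification genes, 13 were higher and 1 lower in Lsd1 KO by edgeR. Glyoxalase Glo1 went from 24.6 ± 3.13 to 138 ± 25.8 CPM (log2 2.49 ± 0.20) and the autophagy receptor Sqstm1 from 18.8 ± 0.650 to 80.2 ± 5.24 CPM (2.09 ± 0.18). Also higher were the glutathione peroxidase Gpx1, from 30.2 to 115 CPM (1.93 ± 0.28), the aldo-keto reductase Akr1b8, from 19.8 to 85.6 CPM (2.11 ± 0.23) and Ptgr1, from 23.9 to 98.5 CPM (2.04 ± 0.26). These 5 and Txnrd1 (1.03 ± 0.22) kept the call with each library left out. The other 7 rises (Cbr1, Ftl1, Gsto2, Hmox1, Keap1, Nqo1 and Sod2) and the fall of Gclm were each lost without at least 2 single libraries (adjusted p up to 0.159, for Cbr1). Cbr1, Ftl1, Hmox1 and Nqo1 also lost the call with the immune covariate, and Cbr1, Ftl1, Gsto2, Nqo1 and Gclm with the length and GC correction.

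Among 21 metallothioneins, zinc transporters and the zinc-sensing factor Mtf1, Mt1, Mt4 (1.79 ± 0.31), Slc39a5 (2.72 ± 0.49) and Slc30a3 (1.24 ± 0.32) were higher, and the zinc exporter Slc30a1 (-1.35 ± 0.20) and Mtf1 (-0.62 ± 0.19) lower. Slc30a3 was lost without Lsd1 KO replicate 2 or Control replicates 1 or 2 (adjusted p up to 0.0796) and Mtf1 in 5 of the 6 leave-one-out fits (up to 0.1). Slc30a3 was also lost with the DESeq2 Wald test and Mtf1 with cyclic loess. Mt2 did not pass (3.67 against 0.710 CPM, adjusted p = 0.117). Of 7 alpha-tubulins, Tuba1a, Tuba1b, Tuba1c (1.52 ± 0.22) and Tuba3a (1.55 ± 0.25) were higher, and of 7 beta-tubulins Tubb2a (0.94 ± 0.17) and Tubb2b (0.79 ± 0.17) were higher and Tubb6 (-1.27 ± 0.19) lower. The 3 subunits of the CDK-activating kinase were higher: Cdk7 at 1143 ± 247 against 490 ± 64.6 CPM (log2 1.22 ± 0.20), Ccnh (1.00 ± 0.23) and Mnat1 (1.20 ± 0.27). Of 4 bromodomain acetyltransferases Ep300 fell from 295 ± 48.9 to 109 ± 2.42 CPM (-1.44 ± 0.18), and Kat2a was lower (-0.66 ± 0.20) but kept the call in 1 of the 6 leave-one-out fits (adjusted p up to 0.168) and lost it with the immune covariate. Of 7 sirtuins Sirt1 was lower, at 67.0 ± 14.7 against 149 ± 15.5 CPM (-1.15 ± 0.20), and Sirt2 (1.07 ± 0.24), Sirt4 (1.38 ± 0.37) and Sirt5 (0.70 ± 0.21) were higher. Sirt4 and Sirt5 kept the call in 3 and 0 of the 6 leave-one-out fits (up to 0.0979 and 0.143), and Sirt5 lost it with the length and GC correction. Of 130 gene families by symbol stem, Zfp passed among genes lower (61 of 309, Fisher adjusted p = 1.37e-04, a test that takes genes as independent) and Taf did not (8 of 22 lower, adjusted p = 0.135). Of these 8 Taf genes, only Taf5l and Taf7 kept the call without Lsd1 KO replicate 3 or without Control replicate 2. By camera the Zfp call was lost with an estimated correlation (adjusted p = 0.155) and without Lsd1 KO replicate 3 or Control replicate 2, which left 33 and 39 Zfp genes lower. None of 20 chromosomes passed, with 15.0% of genes higher on X and 14.6% on chromosome 6 (Fisher adjusted p = 0.176 for both).

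Longer transcripts were lower in Lsd1 KO: among the shortest 25% of transcripts 423 were higher and 174 lower, and among the longest 25% 235 and 485. Length-dependent recovery that differs between libraries may contribute, since the slopes of level on length (log2 per doubling, against the mean of all libraries) overlapped between genotypes, at -0.05, -0.02 and -0.12 in Lsd1 KO and -0.05, 0.11 and 0.12 in Control, with a gap of -0.0350 between the groups. An exact permutation test of the slopes gave p = 0.3, where the smallest possible is 0.1. After the length and GC correction 86.0% of the called genes kept call and direction, and 1227 genes were higher and 1609 lower. How well the correction works on these data is not known, so this share cannot decide whether the trend caused the calls. A biological difference by length remains open.

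Carried-over granulosa or cumulus cells may account for the rise of Cyp19a1 and Ptgs2. The log2 ratio of this pair to 17 other markers was 3.47, 4.27 and 2.81 in Lsd1 KO and 1.09, 1.42 and 1.20 in Control, higher by 2.28, but the pair was picked because it rose most, so this excludes nothing. The ratio of Cyp19a1 to Inha was 15.1, 32.3 and 4.63 in Lsd1 KO and 2.66, 4.27 and 3.24 in Control, and expression in the oocyte was not tested. For the other granulosa markers the mean pairwise correlation of their deviations from group means was 0.258, between the values set for and against carried-over cells, so this stays open. Of the 19 measured markers, 4 were at 10 CPM or more in Control and 1 is in another list; the most abundant that rose, Cyp19a1, was at 324 CPM in Lsd1 KO.

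Genes under the median level (mean of 19.8 CPM) were called more often higher, 736 against 401 (64.7%), than genes over it, 685 against 928 (42.5%; Fisher p = 6.98e-31, odds ratio 2.49; genes are not independent). A difference in depth is an unlikely source, as 65.1% were higher after thinning to the smallest total. Under the immune covariate the share was 65.4%, with 536 higher and 284 lower. Fewer genes passed in both directions with this covariate, so the share alone cannot exclude immune-cell RNA as a source. Cyclic loess gave 58.1% under and 51.7% over the median, against 64.3% and 43.3% for limma-voom without it, so a level-dependent bias between libraries may account for part of the difference and stays open. The length and GC correction gave 58.4% and 33.2%. No biological explanation was tested.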
